A study of Homo sapiens with 8 samples.

How the data were processed

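RNA of DOHH2 cells, labelled as biotin cRNA with an Ambion kit for Illumina arrays per the labels' protocols, was hybridised to 8 bead arrays. The deposited intensity table gives 1 linear intensity per probe for 47231 probes, neither normalised nor background-subtracted, as its values show. Detection p-values and control probes were not analysed here, and the scanner software is not given in the sources used here. It has 10 further unnamed columns, of which 0 hold a value. The deposited value table is on the log2 scale. Quantile normalization of the log2 intensities gave the same values within 0.00126, so those deposited values carry no background correction, and every array has a median of 6.67. What else was done to them is not given in the sources used here.

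Each array was assigned to its group and time from its labels. The arrays of the same time were treated as pairs, since each time point holds 1 array of each treatment. The deviations from the group means correlated across probes between the 2 arrays of a time with r = 0.59, 0.44, 0.68 and 0.48 at 4, 8, 12 and 24 h, all above 0.1. At 24 h the highest correlation with another time was 0.51. No arrays held identical values; the smallest SD of the difference between 2 arrays of a group was 0.11 on the log2 scale.

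Probe genes came from the platform annotation table. Of the probes, 30113 had 1 gene symbol, 8 had several and 17110 had none there, and probes with several or none were not named. Of the named probes 30074 matched the gene table of GRCh38.p14 by gene identifier, and 0 symbols needed an update. That table served only for names, gene lengths and neighbours; the files name no genome build, so no coordinates are given. Older symbols in the gene lists were updated through its synonyms, and 800 of the 853 distinct list entries were on the array.

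The planned design assumed detection p-values. In their absence the brightness of 437 probes of olfactory receptor genes, taken as not expressed in these cells, served as the background. A probe's background p on an array was the share of these probes at least as bright, and a probe was kept where that p was under 0.05 on at least 4 of the 8 arrays. This kept 18640 probes, 13866 of them named. The olfactory probes had median intensities of 82.5 to 102 per array, against medians of 88.6 to 114 over all probes. As foreseen for data without detection p-values, the main normalization was quantile normalization of log2 intensities without background correction. Log2 changes are therefore compressed for dim genes: background correction widened the spread of log2 changes 1.44 times. A gene was represented by its kept probe with the highest mean, which gave 10443 genes, 2711 of them with more than 1 kept probe.

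Tests were run with limma 3.58.1 in R 4.3.3, and figures with matplotlib 3.10.9 in Python 3.11.15. The treatment effect was the coefficient of BAY1238097 against DMSO with the time point as a factor, from lmFit and eBayes. The change of that effect with time was the coefficient of treatment by centred log2 hours, with the same factor. Time trends were slopes on log2 hours in each group, from a model with treatment, log2 hours and their product over all 8 arrays, so that both groups share the estimate of the spread. Adjusted p-values are Benjamini-Hochberg over the genes tested, with a threshold of 0.05. Errors beside log2 changes are standard errors of the moderated fit. The 31 gene lists were tested with camera at a preset correlation of 0.01, adjusted over the lists, beside camera with an estimated correlation and fry. A gene that was above background on 0 of the 4 arrays of a group is given as a bound, and for the others the number of arrays above background is stated where it is under 4 in the text. Their changes are limited by background on the remaining arrays, so the sizes given are not exact.

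The gene lists, the tests, the alternatives and the rule for named genes were fixed before the data were examined. The rule took the 12 largest rises and the 12 largest falls among genes past the threshold with the same sign at all 4 times, MYC, HEXIM1 and every measured BET inhibitor response marker, and up to 4 members with the largest absolute change of each list. For treatment by time and the time trends it took the 5 largest coefficients in each direction. Genes named outside this rule, which are the other members of lists with 5 or fewer calls in a direction and the gene families of the closing observations, were chosen after their values were seen.

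The steps were tested on simulated data with the noise of these arrays and 10443 genes. Of 100 genes changed by 0.5 on the log2 scale by treatment 53% were recovered, and of 100 changed by 1, 85%, with 2.13% false calls among all calls. For treatment by time the shares were 41% and 79%, for the DMSO trend 79% and 99%, and for the BAY1238097 trend 77% and 94%. The trend simulations used the spread left by the model with the time factor, which the trend model lacks, so their shares may be too high. Each simulation changed 100 genes per size, far fewer than the 3161 called for treatment in the real data. The adjusted p depends on how many genes change, so the shares recovered need not hold for the reported fits. All 5 simulated shifted lists were recovered by each of the list tests, and 20 simulations without a shifted list gave 1 call. The simulated noise was independent between genes, so these counts do not cover lists whose members move together. The estimated correlation of the DNA replication list, for example, was 0.73 in the real data.

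The alternatives covered normalization (neqc with an offset of 16 and the olfactory probes as negative probes, with quantile or median scaling, median scaling alone, and the deposited log2 values), the filter on dim probes (none, or a background p under 0.01 on all 8 arrays), every probe on its own, an intensity trend with robust variances, array weights, the model without the time factor, hours in place of log2 hours, other thresholds, and each time point or array left out. The neqc fit with quantile normalization and the median scaling without background correction were added after seeing the data. Dixon's test at 95% confidence was used to find single arrays far from the others of a group.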

Results

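Gene expression was measured in DOHH2, an established human B-cell lymphoma line of germinal centre origin, after exposure to BAY1238097 or to its vehicle DMSO. BAY1238097 inhibits the bromodomains of the BET proteins, which bind acetylated histones at active genes. The series held 8 Illumina bead arrays, 1 for each treatment at 4, 8, 12 and 24 h, so that each group had 4 arrays and no time point was repeated. The dose is not given in the sources used here. The labels do not say that the arrays came from separate cultures, so the p-values measure the spread over the time points of 1 time course, which may be partly technical. The number of arrays limits the precision. The 4 h arrays were the dimmest in both groups, with mean probe intensities of 264 in DMSO and 262 in BAY1238097. At 8, 12 and 24 h the DMSO arrays averaged 383, 419 and 407, against 331, 366 and 334 with BAY1238097. Between 17438 and 19122 of the 47231 probes per array were above background. The first principal component of the normalised values, with 44.5% of the variance, separated the treatments. The second, with 34.2%, fell from 4 h to 12 h in both groups, from 19.7 to -18.8 in DMSO and from 24.4 to -6.66 with BAY1238097, and was -18.4 and -6.98 at 24 h.

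**Figure D1:**
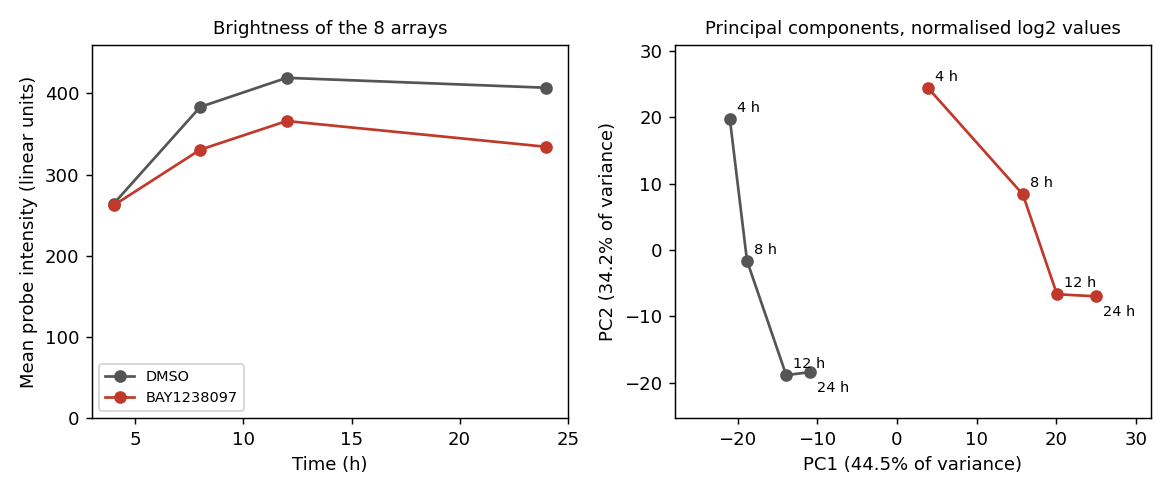
Left, mean probe intensity of each array (linear units) against time in hours for DMSO (grey) and BAY1238097 (red); right, the first and second principal components of the normalised log2 values, each point 1 array labelled with its time. The 4 h arrays were the dimmest of both groups (264 and 262), and the 4 BAY1238097 arrays lie at higher PC1 values than the 4 DMSO arrays.

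The first comparison asked which genes differed between BAY1238097 and vehicle at matched times. The largest rises were in histone genes. H2BC21 rose by 3.04 ± 0.15 on the log2 scale (SE, 4 time points), 8.21-fold, with an adjusted p of 0.000199, and H2BC5 rose by 3.01 ± 0.07, 8.03-fold, with an adjusted p of 2.00e-05. H2AC18 (2.90), H2AC6 (2.64), H2BC11 (2.59), H2AC19 (2.56), H2AC20 (2.13), H2AJ (2.09) and H2BC8 (2.05) followed. The other genes among the 12 largest rises were CCL5, a chemokine that attracts T cells (2.48 ± 0.19), PEG10, an imprinted gene derived from a retrotransposon (2.03 ± 0.13), and DCXR, a carbonyl reductase (1.87 ± 0.12). All 12 rose at each of the 4 time points, as the rule for naming them required. In all, 3161 of 10443 genes tested passed an adjusted p of 0.05 in limma, 1620 higher and 1541 lower with BAY1238097, and 3088 of them had the same sign at all 4 times. An absolute log2 change of at least 1 was reached by 54 of the higher and 81 of the lower genes. Without the 8 h arrays 1276 genes passed and without the 12 h arrays 1291. With the time point left out of the model 1485 passed, and with array weights 4885. The balance of directions depended on the scaling, since median scaling gave 807 higher and 2426 lower genes, and background correction with median scaling gave 1037 and 2213. Brightness went with treatment as well. Over the probes kept, the treated arrays were dimmer than their DMSO partners by -0.23, -0.21 and -0.31 on the log2 scale at 8, 12 and 24 h. At 4 h the difference was -0.015. The part of brightness in the treatment calls was not tested.

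The largest fall was in TNFRSF17, the BCMA receptor of plasma cells and late B cells, which fell by 2.52 ± 0.10 (5.75-fold lower, adjusted p = 0.000126). BBOX1, an enzyme of carnitine synthesis, fell by 2.26 ± 0.33, by 0.82 at 4 h and by 2.59 to 2.83 later. MLKL, the effector of necroptosis, fell by 1.99 ± 0.12 and was above background on 1 of the 4 BAY1238097 arrays. PVRIG, an immune checkpoint receptor, fell by 1.92 ± 0.30 and was above background on 2 of the 4. On the other arrays background limits how low their values can be, so neither size is exact. Further falls were seen in PLD6 (-1.89), the cytoskeletal gene COBL (-1.84), GAPT (-1.67), NOL4 (-1.61), CCDC112 (-1.55), the peptide transporter SLC15A3 (-1.50) and the antiviral enzyme OAS2 (-1.46). The chemokine-scavenging receptor ACKR4 was not above background on any BAY1238097 array and was at least 2.40-fold lower (adjusted p = 0.00144), a bound taken against the lowest normalised signal above background on each array. All 12 genes fell at each of the 4 time points, again as the naming rule required. The call of SLC15A3 was lost without the 8 h arrays (adjusted p = 0.0509).

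**Figure D2:**
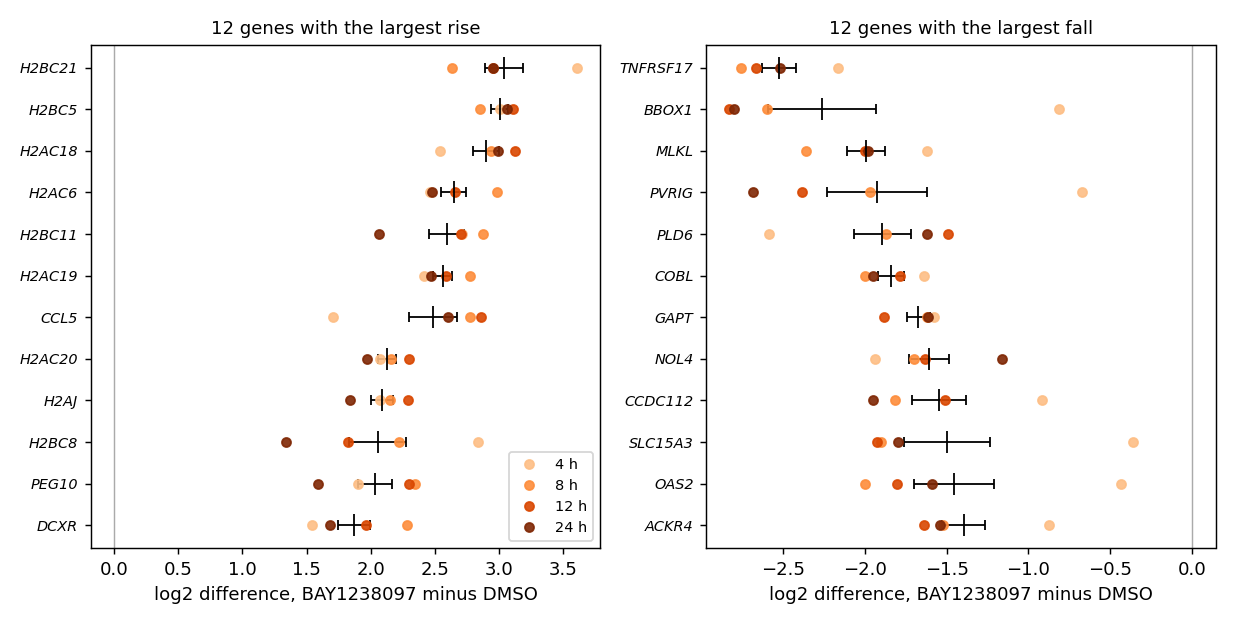
log2 difference between BAY1238097 and DMSO (x axis) for the 12 genes with the largest rise (left) and the 12 with the largest fall (right). Each coloured point is 1 time point and the black tick is the mean of the 4. The bar is the standard error of the moderated fit, not that of the 4 points alone. H2BC21 averaged 3.04 and TNFRSF17 -2.52, and all points of a panel lie on the same side of 0, which the rule for choosing the genes required.

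Histone genes rose as a group. Of 22 measured genes in a list fixed before the data were examined, 19 rose and 0 fell over all genes tested (20 and 0 adjusted over the list alone), with a median log2 change of 1.70 and medians of 1.63, 1.78, 1.77 and 1.68 at 4, 8, 12 and 24 h. The camera adjusted p was 9.77e-16, and the adjusted p was 0.116 with an estimated correlation. Many histone genes are near-identical copies, such as H2AC18 and H2AC19, and 1 probe can bind transcripts of several. Of the 10 BET inhibitor response markers usually raised, 8 rose and 0 fell (10 and 0 adjusted over the list alone), with a median of 1.79 (camera adjusted p = 6.36e-09, adjusted p = 0.116 with an estimated correlation). They included 6 histone genes, among them H2BC12 (1.83 ± 0.08) and the linker histone H1-2 (1.75 ± 0.23), the thioredoxin inhibitor TXNIP (1.16 ± 0.07) and SERPINI1 (0.60 ± 0.08), which was above background on 3 of 4 DMSO arrays. HEXIM1, a repressor of the elongation factor P-TEFb, had a log2 change of 0.22 ± 0.09 (adjusted p = 0.0940) and ZCCHC24 one of 0.23 ± 0.08 (adjusted p = 0.0690). Neither passed. Both did after background correction with quantile normalization (0.57 and 0.56, adjusted p = 0.0369 and 0.0234) or median scaling (0.47 and 0.47, adjusted p = 0.0326 and 0.0268), and with a variance trend (0.0452 and 0.0349), and without the 4 h arrays the changes were 0.13 and 0.15 (0.147 and 0.0978). Of 22 genes of BET proteins and the P-TEFb machinery, 6 rose and 0 fell (6 and 0 adjusted over the list alone). BRD2 rose by 0.53 ± 0.06, AFF1 by 0.45 ± 0.08, AFF4 by 0.46 ± 0.11 and CDK9 by 0.44 ± 0.11. The median of that list was 0.14 (camera adjusted p = 0.0305, adjusted p = 0.414 with an estimated correlation). Its call was lost without the 4 h arrays (median 0.067, adjusted p = 0.0659), with array weights (0.0580) and under median scaling with or without background correction (0.0672 and 0.0867). AFF4 lost its call without the 12 or 24 h arrays (adjusted p = 0.0988 and 0.0611), CDK9 without the 8 h arrays (0.115), both under median scaling (0.0939 and 0.136, and 0.0617 and 0.0798 with background correction), and BRD2 with the time point left out of the model (0.222).

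MYC, the transcription factor that drives growth in many lymphomas, fell by 1.13 ± 0.21 on the log2 scale (2.19-fold lower, adjusted p = 0.0104). Its difference was -1.97 at 4 h, -1.16 at 8 h, -0.82 at 12 h and -0.57 at 24 h. Without the 8 h arrays the fall was 1.12 with an adjusted p of 0.0558. Of 8 measured BET inhibitor response markers usually lowered, 5 fell and 0 rose, the same counts as adjusted over the list alone. The interleukin receptor IL7R fell by 1.30 ± 0.11, the cell cycle kinase CDK6 by 0.49 ± 0.07, E2F2 by 0.36 ± 0.07 and the chemokine receptor CCR2 by 0.24 ± 0.06. CCR2 was above background on 1 of 4 BAY1238097 arrays and lost its call without the 8, 12 or 24 h arrays (adjusted p = 0.106, 0.0915 and 0.0618), and E2F2 without the 8 h arrays (0.0605). The calls of CDK6, E2F2 and CCR2 were lost with the time point left out of the model (adjusted p = 0.287, 0.104 and 0.289). BCL2, the anti-apoptotic gene, did not pass (-0.15 ± 0.15), and its mean was 0.031 without the 4 h arrays. FOSL1 (0.10), above background on 2 of 4 DMSO arrays, did not pass either. The chemokine receptor CCR1 (-0.18, adjusted p = 0.107), above background on 3 of 4 DMSO arrays and 1 of 4 BAY1238097 arrays, passed only after background correction with quantile normalization (0.0494) or median scaling (0.0398) and with a variance trend (0.0377). The list's camera adjusted p was 0.00500, and the adjusted p = 0.298 with an estimated correlation.

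Genes of ribosome biogenesis and the nucleolus, listed as MYC targets, fell together. Of 41 measured, 34 fell and 0 rose (35 and 0 adjusted over the list alone), with a median of -0.47 and medians of -0.44, -0.62, -0.52 and -0.47 over time. NOP16 fell by 1.26 ± 0.07, RRS1 by 1.04 ± 0.09, the snoRNP component GAR1 by 1.01 ± 0.06 and the helicase DDX21 by 0.85 ± 0.08. The camera adjusted p was 9.77e-16, and the adjusted p = 0.154 with an estimated correlation. Of 38 MYC targets of metabolism and translation, 18 fell and 1 rose (26 and 1 adjusted over the list alone), with medians of -0.10 at 4 h and -0.48 at 24 h. Cyclin D2 (CCND2) fell by 1.15 ± 0.21, NME1 by 0.89 ± 0.15, prohibitin PHB1 by 0.81 ± 0.09 and the methyltransferase PRMT5 by 0.73 ± 0.07. The camera adjusted p was 1.49e-07, the adjusted p = 0.449 with an estimated correlation, and 0.0572 by fry. CCND2 lost its call without the 12 h arrays (adjusted p = 0.0523) and PHB1 with the time point left out of the model (0.128). The list of cytosolic ribosomal protein genes did not pass by camera, with 4 of 48 higher and 2 lower (1 and 2 adjusted over the list alone). Their median was 0.019, their mean -8.02e-05 and the camera direction up (adjusted p = 0.542). The list passed by fry (adjusted p = 0.0264) and under median scaling without and with background correction (median 0.080 and 0.13, adjusted p = 9.53e-05 and 0.000758). RPL29 (-1.30 ± 0.25) and RPS7 (-0.93 ± 0.19) fell and RPS23 rose (0.50 ± 0.10), and probes of ribosomal protein genes can also bind processed copies. All 3 calls were lost without the 8 h arrays (adjusted p = 0.0556, 0.0642 and 0.0573), those of RPL29 and RPS7 without the 12 h arrays (0.0554 and 0.0700), and that of RPS23 with the time point left out of the model (0.197) and under median scaling without and with background correction (0.119 and 0.0763).

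Several genes of B-cell identity and signalling fell. Of 14 plasma cell markers, 6 fell and 1 rose (8 and 1 adjusted over the list alone), with a median of -0.28 (camera adjusted p = 0.00115, adjusted p = 0.299 with an estimated correlation). Besides TNFRSF17, they included FKBP11, a chaperone of the secretory pathway (-1.20 ± 0.16), MZB1, which assists antibody folding (-1.32 ± 0.32), and the costimulatory receptor CD27 (-0.94 ± 0.21). MZB1 and CD27 lost their calls without the 8 h arrays (adjusted p = 0.0750 and 0.0831) or the 12 h arrays (0.0958 and 0.0781), and MZB1 without a filter on dim probes (0.0530). FKBP11 and CD27 lost theirs with the time point left out of the model (0.0595 and 0.0583). Of 27 genes of B cell receptor signalling, 9 fell and 3 rose (10 and 3 adjusted over the list alone), with a median of -0.14 (camera adjusted p = 0.0390, adjusted p = 0.299 with an estimated correlation). The kinase BTK fell by 0.86 ± 0.12, RASGRP3 by 0.86 ± 0.13 and the inhibitory receptor FCGR2B by 0.69 ± 0.07. The phosphatase PTPN6 fell by 0.92 ± 0.08 and was above background on 1 of 4 BAY1238097 arrays. That list's call was lost without the 4 h arrays (adjusted p = 0.0623) or the 8 h arrays (0.0524), with the stricter background filter (median -0.040, adjusted p = 0.313) and under median scaling (0.0867). Of 23 germinal centre B cell markers, 8 fell and 3 rose (10 and 4 adjusted over the list alone), with a median of -0.14 (camera adjusted p = 0.0392, adjusted p = 0.299 with an estimated correlation). The list's call was lost without the 4 h arrays (median -0.11, adjusted p = 0.151) or the 8 h arrays (median -0.027, adjusted p = 0.0593), with the stricter filter (0.325), array weights (0.0719) or the time point left out of the model (0.0548), and under median scaling without and with background correction (0.185 and 0.0601). The migration receptor P2RY8 fell by 1.12 ± 0.10 and IRAG2 by 0.63 ± 0.07, while the transcription factor IRF8 rose by 0.63 ± 0.11. SERPINA9 was not above background on any BAY1238097 array and was at least 1.52-fold lower (adjusted p = 0.00338). IRF8 lost its call without the 8 h arrays (adjusted p = 0.0555).

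Among interferon response and MHC class II genes more fell than rose, and the medians of both lists were lower from 8 h onwards than at 4 h. Of 32 interferon response genes, 17 fell and 3 rose (22 and 3 adjusted over the list alone), with medians of -0.14 at 4 h and -0.49, -0.50 and -0.70 later. ISG20 fell by 1.20 ± 0.14 and MX1 by 1.12 ± 0.16, both antiviral effectors, whereas IFIT2 rose by 1.07 ± 0.13. The camera adjusted p was 2.17e-06, and the adjusted p = 0.369 with an estimated correlation. Of 16 genes of MHC class II presentation, 6 fell and 0 rose (11 and 0 adjusted over the list alone), with medians of 0.044, -0.39, -0.49 and -0.62 over time. HLA-DMB, which loads peptides, fell by 1.27 ± 0.18, and CIITA, the class II transactivator, fell by 0.77 ± 0.09 and was above background on 1 of 4 BAY1238097 arrays. HLA-DOB fell by 0.72 ± 0.20. The camera adjusted p of the list was 0.000422, the adjusted p = 0.449 with an estimated correlation, and 0.0819 by fry. The call of HLA-DOB was lost without the 8, 12 or 24 h arrays (adjusted p = 0.107, 0.146 and 0.0951) and without a filter on dim probes (0.0807). ISG20, MX1, HLA-DMB and HLA-DOB lost their calls with the time point left out of the model (adjusted p = 0.126, 0.0554, 0.139 and 0.103).

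Other signalling lists went both ways. Of 30 NF-kappaB targets, 6 rose and 5 fell (the same counts adjusted over the list alone). The inhibitor NFKBIA rose by 1.10 ± 0.12, GADD45B by 0.9991 ± 0.09, the chemokine CCL3 by 0.81 ± 0.18 and NFKBIZ by 0.73 ± 0.14. The median of -0.041, the mean of 0.030 and the camera direction (down, adjusted p = 0.998) differed in sign, and the median was 0.10 with the stricter background filter and 0.027 without the 4 h arrays. CCL3 has near-identical copies. Of 18 genes of MYD88 and Toll-like receptor signalling, 3 rose and 6 fell (4 and 6 adjusted over the list alone). TLR7, a sensor of single-stranded RNA, fell by 0.81 ± 0.09 and IRAK1 by 0.74 ± 0.20, while IRF7 (0.76 ± 0.18) and the kinase MAP3K7 (0.60 ± 0.07) rose. The median was 0.017, the mean -0.082 and the camera direction down (adjusted p = 0.654). Of 20 genes of JAK and STAT signalling, 7 rose and 2 fell, the same counts as adjusted over the list alone (median 0.040, camera adjusted p = 0.368). IL10RB rose by 0.72 ± 0.08, PIM1 by 0.65 ± 0.14 and JAK1 by 0.52 ± 0.10, and STAT5A fell by 0.68 ± 0.11. Calls were lost without the 8 h arrays for CCL3, NFKBIZ, IRAK1, IRF7 and JAK1 (adjusted p = 0.0796, 0.0546, 0.140, 0.0954 and 0.0641), without the 12 h arrays for these and PIM1 (0.0771, 0.0571, 0.125, 0.0732, 0.0522 and 0.0587), and without the 24 h arrays for IRAK1 (0.0866). With the time point left out of the model CCL3, IRF7, STAT5A and JAK1 lost theirs (0.271, 0.0860, 0.0602 and 0.0721), as did IRAK1 without a filter on dim probes (0.0717) and IRF7 under median scaling (0.0774).

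Among genes of growth arrest, lysosomes and early responses more rose than fell. Of 19 genes of cell cycle inhibition and quiescence, 8 rose and 0 fell (9 and 0 adjusted over the list alone), with a median of 0.26 (camera adjusted p = 0.000125, adjusted p = 0.154 with an estimated correlation). The CDK4 and CDK6 inhibitor CDKN2D rose by 0.95 ± 0.07, KLF6 by 0.93 ± 0.10 and the antiproliferative gene BTG1 by 0.84 ± 0.07. Of 35 genes of lysosome and autophagy, 19 rose and 1 fell (22 and 1 adjusted over the list alone), with a median of 0.30 (camera adjusted p = 2.17e-06, adjusted p = 0.302 with an estimated correlation). The autophagy receptor SQSTM1 rose by 1.15 ± 0.08, the sialidase NEU1 by 0.99 ± 0.09, the cholesterol transporter NPC1 by 0.86 ± 0.06 and MAP1LC3B by 0.81 ± 0.07. Of 21 immediate early genes, 11 rose and 1 fell (13 and 2 adjusted over the list alone), with a median of 0.44 (camera adjusted p = 0.000289, adjusted p = 0.299 with an estimated correlation) and of 0.26 without the 4 h arrays (adjusted p = 0.000857). ZFP36, which destabilises cytokine mRNAs, rose by 1.69 ± 0.08, the activation marker CD69 by 1.63 ± 0.14 and JUN, above background on 3 of 4 DMSO arrays, by 1.32 ± 0.10, and the gene that fell was MYC. Of 21 p53 targets, 9 rose and 2 fell, the same counts as adjusted over the list alone, with a median of 0.25 (camera adjusted p = 0.0305, adjusted p = 0.299 with an estimated correlation) and of 0.13 without the 4 h arrays (adjusted p = 0.0305). GADD45A rose by 0.87 ± 0.12, TP53INP1 by 0.77 ± 0.16 and XPC by 0.60 ± 0.10, and AEN fell by 0.67 ± 0.07. That list lost its call without the 8 h arrays (adjusted p = 0.0524) and with the stricter filter (0.115). TP53INP1 lost its call without the 12 h arrays (0.0523), and TP53INP1 and AEN with the time point left out of the model (0.0573 and 0.0625).

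The lists of apoptosis regulators did not pass. Of 12 pro-apoptotic BCL2 family genes, 2 rose and 1 fell, the same counts as adjusted over the list alone. BNIP3L rose by 0.78 ± 0.11 and PMAIP1 by 0.61 ± 0.13, and BID fell by 0.62 ± 0.07. The median was 0.015 and the mean 0.054 while the camera direction was down (adjusted p = 0.998), and the median was -0.072 under median scaling. Of 10 anti-apoptotic regulators, 2 rose and 1 fell, again the same counts over the list alone. MCL1 rose by 0.80 ± 0.13 and BCL2L1 fell by 0.48 ± 0.13. The median was -0.034, the mean 0.027 and the camera direction up (adjusted p = 0.998). PMAIP1 lost its call without the 12 h arrays (adjusted p = 0.0731) and BCL2L1 without the 4, 8 or 12 h arrays (0.0539, 0.124 and 0.130) and without a filter on dim probes (0.0648). BNIP3L and BCL2L1 lost theirs with the time point left out of the model (0.192 and 0.293).

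The median of DNA replication genes and E2F targets was lower late in the time course. The medians were 0.13, -0.085, -0.18 and -0.60 at 4, 8, 12 and 24 h, and of 45 measured genes 6 fell and 1 rose (5 and 1 adjusted over the list alone). RFC3 fell by 0.85 ± 0.17, POLE2 by 0.80 ± 0.20 and the uracil glycosylase UNG by 0.67 ± 0.16, while RRM2, a subunit of ribonucleotide reductase, rose by 0.59 ± 0.15. The list's camera adjusted p was 0.0150, the adjusted p = 0.843 with an estimated correlation, 0.508 by fry and 0.542 without the 24 h arrays (median -0.063). All 4 gene calls were lost without the 12 h arrays (adjusted p = 0.0530, 0.0825, 0.0822 and 0.0855), and those of POLE2, UNG and RRM2 without the 8 h arrays (0.0791, 0.0826 and 0.110). Without the 24 h arrays POLE2 fell by 0.53. UNG and RRM2 lost theirs with the time point left out of the model (0.231 and 0.0624), POLE2 and RRM2 without a filter on dim probes (0.0568 and 0.0516), and RRM2 under median scaling without and with background correction (0.165 and 0.101). Of 37 mitosis genes, 2 rose and 1 fell (0 and 0 adjusted over the list alone in limma). The median was 0.016 (camera adjusted p = 0.654). It was -0.14 and -0.12 under median scaling without and with background correction, -0.058 without the 8 h arrays, and 0.14 without the 24 h arrays, where the list passed (adjusted p = 0.00535). ANLN (0.38 ± 0.11) and CENPE (0.36 ± 0.11) rose. Both calls were lost without the 4, 8 or 12 h arrays (adjusted p from 0.0662 to 0.178), with the time point left out of the model (0.0698 and 0.217), without a filter on dim probes (0.0850 and 0.0814) and under median scaling without (0.209 and 0.306) and with background correction (0.118 and 0.186).

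Metabolic and stress lists held few calls. Of 36 genes of oxidative phosphorylation, 7 fell and 1 rose, the same counts as adjusted over the list alone, with a median of -0.11 (camera adjusted p = 0.0423, adjusted p = 0.680 with an estimated correlation). ATP5MC1 fell by 0.72 ± 0.13 and NDUFC1 by 0.39 ± 0.06. The list's call was lost without the 8, 12 or 24 h arrays (adjusted p = 0.0546, 0.0671 and 0.275), after background correction with either scaling (0.0966 and 0.139), with the stricter filter (0.0617), with the time point left out of the model (0.0802) and by fry (0.180). ATP5MC1 lost its call without the 8 or 12 h arrays (0.0558 and 0.0536), and ATP5MC1 and NDUFC1 with the time point left out of the model (0.0674 and 0.114). Of 19 glycolysis genes, 3 fell and 1 rose, the same counts as adjusted over the list alone (median -0.17, camera adjusted p = 0.184, and 0.0149 without the 4 h arrays). Hexokinase HK2 fell by 0.80 ± 0.14, PFKP by 0.50 ± 0.11 and PFKM by 0.48 ± 0.09, and PKM rose by 0.42 ± 0.09. PFKP, PFKM and PKM lost their calls without the 8 h arrays (adjusted p = 0.0558, 0.0602 and 0.0607) or the 12 h arrays (0.0600, 0.0615 and 0.0813). PFKP and PKM lost theirs with the time point left out of the model (0.0548 and 0.245), and PKM under median scaling without and with background correction (0.259 and 0.170).

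Of 20 genes of cholesterol synthesis, 3 rose and 2 fell, the same counts as over the list alone. LSS (0.61 ± 0.07) and TM7SF2 (0.73 ± 0.17) rose and ACAT2 (-0.63 ± 0.14) fell. The median was -0.026, the mean 0.032 and the camera direction down (adjusted p = 0.998), and the median was -0.21 under median scaling and 0.091 without the 24 h arrays. TM7SF2 and ACAT2 lost their calls without the 8 h arrays (adjusted p = 0.0974 and 0.0675) or the 12 h arrays (0.0832 and 0.0535) and with the time point left out of the model (0.0543 and 0.113), and TM7SF2 under median scaling (0.0723). Of 26 heat shock and unfolded protein response genes, 2 rose and 4 fell, the same counts as adjusted over the list alone (median -0.13, camera adjusted p = 0.197). The list passed without the 4 h arrays (adjusted p = 0.0110) and with array weights (0.0476). The stress factor ATF3 rose by 1.32 ± 0.25, with differences of 2.22 at 4 h and 0.58 at 24 h. The pseudokinase TRIB3 fell by 1.13 ± 0.08 and SDF2L1 by 0.78 ± 0.08. Asparagine synthetase ASNS did not pass (0.57 ± 0.21, adjusted p = 0.0833) but did without the 24 h arrays (0.85, adjusted p = 0.00545) and with array weights (0.0175). ATF3 lost its call without the 8 h arrays (0.0597), and ATF3 and SDF2L1 with the time point left out of the model (0.0537 and 0.156).

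Markers of other cell types were mostly not above background. Of 22 T and NK cell markers, 3 were measured, of which 2 fell and 0 rose, the same counts as adjusted over the list alone (camera adjusted p = 0.0305, adjusted p = 0.378 with an estimated correlation). CD247 fell by 0.97 ± 0.09 and was above background on 2 of 4 BAY1238097 arrays. TRAT1, above background on none of them, was at least 1.82-fold lower (adjusted p = 0.00193). The list lost its call without a filter on dim probes (median -0.013, adjusted p = 0.212) and under median scaling (0.101). The 4 measured myeloid markers and the 2 measured stromal, endothelial and epithelial markers included 0 called genes, also when adjusted over the list alone (camera adjusted p = 0.880 and 0.542). Of 11 reference genes, 1 rose, GUSB (0.40 ± 0.07), also when adjusted over the list alone (median 0.062, camera adjusted p = 0.654). GUSB lost its call without the 8 or 12 h arrays (adjusted p = 0.0524 and 0.0535) and under median scaling without and with background correction (0.0807 and 0.0980). In total camera placed 18 of 31 lists past the threshold, 7 higher and 11 lower, and 0 of 31 with an estimated correlation, while fry, a test of each list's own direction, placed 15. The estimated form also lost lists whose correlation lay below the preset 0.01. The raised BET inhibitor response markers had -0.048, and their unadjusted camera p went from 6.15e-10 to 0.00751. The quiescence list had -0.033, with 2.83e-05 and 0.0199. Correlation among members does not account for these lost calls. With the time point left out of the model the real grouping of the arrays moved 16 lists and another grouping moved 17, and with the time point in the model these were 18 and at most 14 over the groupings that part every time point.

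Where a list held 5 or fewer calls in a direction, the members outside the naming rule were chosen after their values were seen. Those that rose were ODC1 (0.33) among MYC targets of metabolism and translation, PRKCB (0.36), PIK3R1 (0.34) and LYN (0.32) in B cell receptor signalling, CD38 (0.38) in the germinal centre list, IRF4 (0.49) in the plasma cell list, PELI1 (0.35) in Toll-like receptor signalling, IFI6 (0.47) among interferon genes, BAG3 (0.27) among anti-apoptotic regulators, HSD17B7 (0.40) in cholesterol synthesis, NDUFB5 (0.27) in oxidative phosphorylation, RPL14 (0.43), RPL7 (0.26) and RPL7A (0.21) in the ribosome and HSP90B1 (0.28) among heat shock genes. The germinal centre gene LMO2 was not above background on any DMSO array and was at least 1.10-fold higher with BAY1238097 (adjusted p = 0.0243). Those that fell were CENPF (-0.28) in mitosis, NFKBIE (-0.65), TRAF1 (-0.48) and IRF1 (-0.37) among NF-kappaB targets beside STAT5A and BCL2L1, IL21R (-0.46, above background on 3 of 4 BAY1238097 arrays) in JAK and STAT signalling, TRIAP1 (-0.48) among p53 targets, CYP51A1 (-0.24) in cholesterol synthesis, CTSS (-0.29, 2 of 4 BAY1238097 arrays) in the lysosome list, and XBP1 (-0.32) and HSP90AA1 (-0.31) among heat shock genes. The third interferon gene that rose was IRF7. Each of these calls except those of IRF7, STAT5A, BCL2L1 (given above) and TRIAP1 was lost without the 8 or the 12 h arrays (adjusted p from 0.0503 to 0.188), those of PRKCB, BAG3, CYP51A1 and RPL7A also without the 4 h arrays (0.0513 to 0.0602), and ODC1 had 0.22 without them, and those of ODC1, CENPF, PRKCB, LYN, CD38, LMO2, HSD17B7, CYP51A1, CTSS, RPL14, RPL7, RPL7A and HSP90AA1 also without the 24 h arrays (0.0582 to 0.131). With the time point left out of the model all were lost but LMO2, PELI1, IL21R and HSP90B1 (0.0643 to 0.812), and under median scaling the rises other than PIK3R1 and LMO2 and the fall of HSP90AA1 were lost (0.0978 to 0.684). With background correction as well the same calls except that of BAG3 were lost (0.0888 to 0.515). Background correction with quantile normalization lost those of ODC1, PRKCB, LYN, CD38, NDUFB5, RPL14, RPL7, RPL7A, HSP90B1, CENPF and HSP90AA1 (0.0505 to 0.133), and the fit without a filter on dim probes those of ODC1, PRKCB, CD38, IFI6, HSD17B7, RPL14 and HSP90AA1 (0.0566 to 0.0923). A variance trend lost RPL7, RPL7A, CENPF and CYP51A1 (0.0503 to 0.0584), and the stricter filter lost RPL7A (0.0555).

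**Figure D3:**
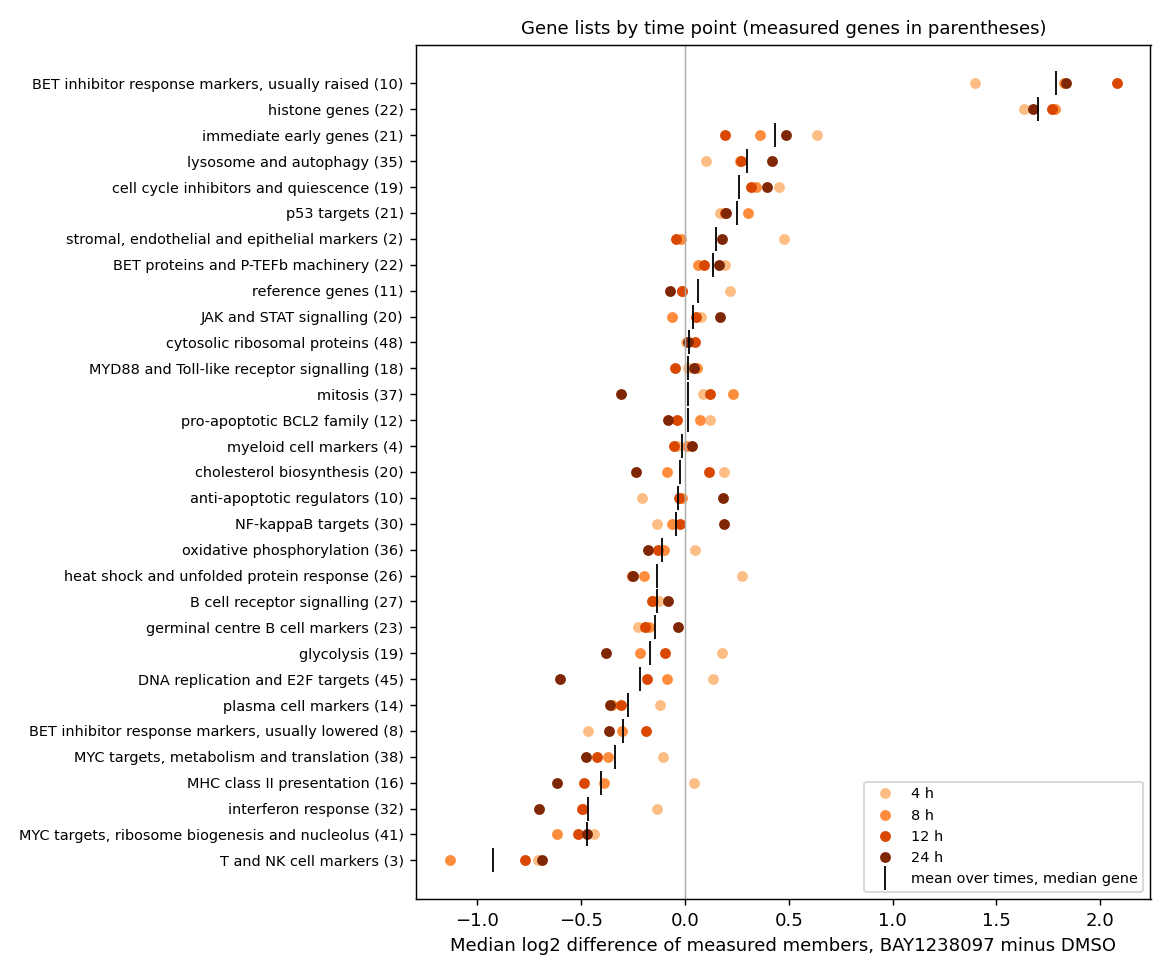
Median log2 difference between BAY1238097 and DMSO (x axis) over the measured members of each of the 31 gene lists; coloured points are the 4 time points and the black tick is the median of the members' means over the 4. The histone list lies between 1.63 and 1.78 at every time, whereas the DNA replication list goes from 0.13 at 4 h to -0.60 at 24 h.

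At single time points the differences have no test, since each rests on 1 array per treatment. The number of genes higher by at least 1 on the log2 scale was 85, 73, 69 and 111 at 4, 8, 12 and 24 h, and the number lower by as much was 74, 143, 121 and 174. The differences correlated across genes with r = 0.65 between 4 and 8 h, 0.88 between 8 and 12 h, 0.84 between 12 and 24 h and 0.46 between 4 and 24 h. Genes are not independent replicates, so these values only describe the profiles.

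The second comparison asked which treatment effects grew or shrank over time. The difference between BAY1238097 and DMSO rose with each doubling of time for the regulators RGS1, CBLB, PRDM1, CFLAR and PIK3CG, by 0.74 ± 0.12, 0.72 ± 0.08, 0.67 ± 0.06, 0.63 ± 0.06 and 0.63 ± 0.08 on the log2 scale. For RGS1, PRDM1 and CFLAR the larger part was a fall in DMSO, with slopes of -0.46, -0.42 and -0.51 there and of 0.28 (adjusted p = 0.0949), 0.25 and 0.12 (adjusted p = 0.185) with BAY1238097, whereas CBLB and PIK3CG had 0.043 and -0.032 in DMSO and 0.76 and 0.60 with BAY1238097. CBLB, a ubiquitin ligase that restrains antigen receptor signals, went from a difference of -0.22 at 4 h to 1.69 at 24 h (adjusted p = 0.0296). PRDM1, the transcription factor of plasma cell differentiation, went from -1.12 to 0.61. FASN, the fatty acid synthase, had a slope of -0.84 ± 0.11 per doubling, from 0.91 at 4 h to -1.32 at 24 h (adjusted p = 0.0309). MZB1 (-0.84 ± 0.08), the metallothionein MT1X (-0.79 ± 0.08), PVRIG (-0.77 ± 0.12) and VPREB3 (-0.77 ± 0.13) had the next most negative slopes. The fall of MYC narrowed by 0.54 ± 0.08 per doubling (adjusted p = 0.0320). At the other MYC probe the difference went from -2.01 at 4 h to -0.70 at 24 h, with DMSO values of 11.29 and 10.33 and BAY1238097 values of 9.29 and 9.63, whereas at the probe reported here DMSO had 11.61 and 11.73 and BAY1238097 9.64 and 11.15. In all, 367 of 10443 genes passed, 190 with a positive and 177 with a negative slope, and 86 of them also differed between treatments on average. Several other settings gave no calls. In limma 0 genes passed after background correction with either scaling, with array weights, with hours in place of their logarithm and without the time factor, against 2252 at an unadjusted p under 0.05 in the fit reported here, and median scaling alone gave 247, 38 positive and 209 negative, without RGS1 (adjusted p = 0.0544). After background correction with quantile normalization the slopes were 0.91 for CBLB, -1.03 for MZB1, -1.18 for VPREB3, -1.32 for PVRIG and 0.58 for MYC, and the adjusted p-values of the 11 genes named here were 0.0577 to 0.0676, against 0.0710 to 0.0936 after background correction with median scaling, 0.0526 to 0.0940 with array weights and 0.113 to 0.250 without the time factor. VPREB3 was lost without a filter on dim probes (adjusted p = 0.0547). Leaving out the 4, 8, 12 or 24 h arrays gave 927, 952, 157 and 1300 genes, and without the 4 h arrays the slopes were -0.51 for FASN, -0.43 for PVRIG, -0.38 for VPREB3 and 0.36 for MYC. The treated arrays were also dimmer than their DMSO partners, by more at 8, 12 and 24 h (-0.23, -0.21 and -0.31 on the log2 scale, over the probes kept) than at 4 h (-0.015).

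**Figure D4:**
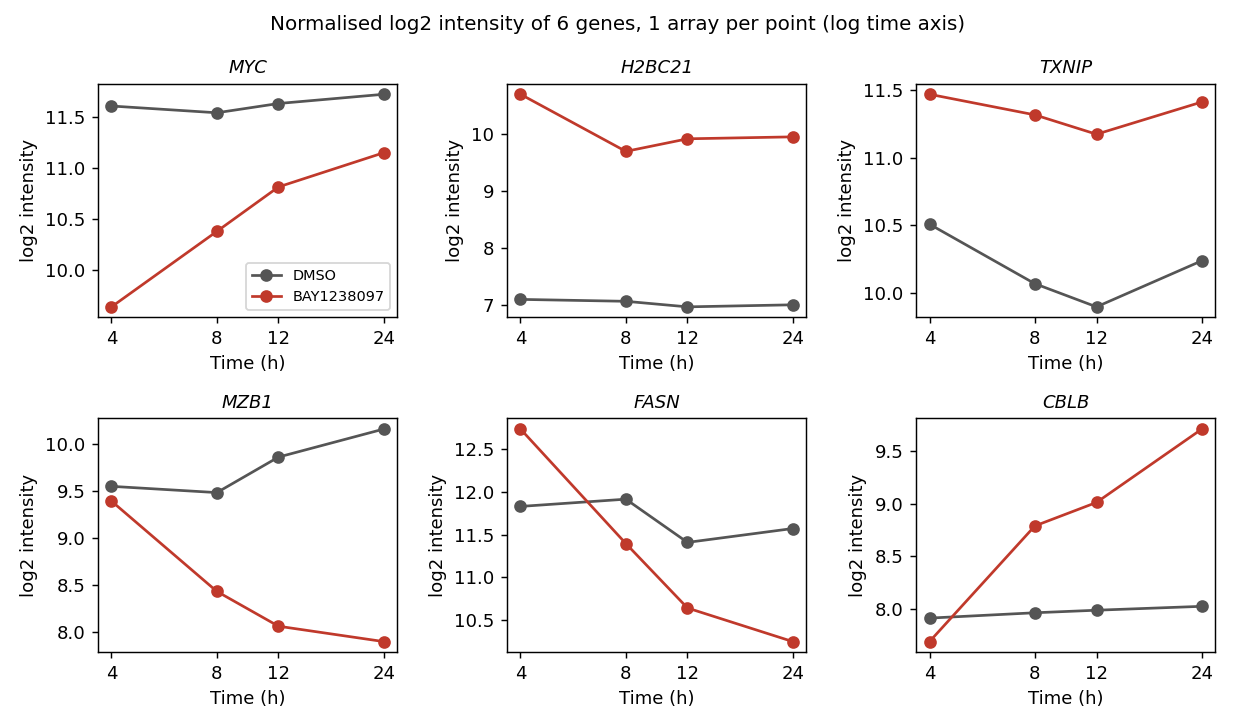
Normalised log2 intensity (y axis) of 6 genes against time in hours on a log axis, in DMSO (grey) and BAY1238097 (red); each point is 1 array. The difference of MYC goes from -1.97 at 4 h to -0.57 at 24 h, and that of FASN from 0.91 to -1.32, while H2BC21 and TXNIP stay higher with BAY1238097 at all 4 times.

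The last comparisons followed each group over time. In DMSO the hypoxia- and stress-responsive gene ADM rose by 0.86 ± 0.18 per doubling of time, ANKRD37 by 0.82 ± 0.13, S100A4 by 0.79, UBA1 by 0.76 and EIF5A by 0.73. The chemokine genes CCL4L1 (-1.03 ± 0.17), CCL3L3 (-0.9995), CCL3L1 (-0.87) and CCL3 (-0.81) and the activation marker CD83 (-0.84) fell. These chemokine genes are near-identical copies whose probes may bind each other's transcripts. The DMSO arrays also brightened, by 0.74 on the log2 scale from 4 to 12 h over the probes kept, and its part in these slopes was not tested. Of 10443 genes, 809 had a slope past the threshold in DMSO, 373 rising and 436 falling. None passed without the 4 h or the 8 h arrays, where limma gave 0 genes (3078 at an unadjusted p under 0.05 with all arrays), 229 passed without the 12 h arrays and 2156 without the 24 h arrays. In BAY1238097, ANKRD37 rose by 0.84 ± 0.13 per doubling, RNA18SN5, above background on 3 of 4 arrays of each group, by 0.82, CITED2 by 0.82, CBLB by 0.76 and SNORD13 by 0.70, and MT1X fell by 1.33 ± 0.08, FASN fell by 0.98 ± 0.12, CCDC106 fell by 0.88, VPREB3 fell by 0.87 and the interferon-induced chemokine CXCL9 fell by 0.87. In this group 954 genes passed, 515 rising and 439 falling, with 2, 1, 349 and 1447 without the 4, 8, 12 and 24 h arrays. The drift was largely shared, since 90.0% of the genes called in DMSO had the same sign of slope with BAY1238097. ADM and S100A4 lost their DMSO slopes without the 12 h arrays (adjusted p = 0.0549 and 0.0524) or the 24 h arrays (0.216 and 0.0633), and ANKRD37 its slope with BAY1238097 without the 24 h arrays (0.0595). Without the 4 or 8 h arrays all the DMSO slopes named here (adjusted p from 0.127 to 0.563) and those with BAY1238097 other than MT1X (0.0547 to 0.337) were lost. Without the 4 h arrays the DMSO slopes were 1.30 for ADM, 0.47 for UBA1, 0.40 for EIF5A, -0.60 for CCL4L1, -0.66 for CCL3L3, -0.51 for CCL3L1 and -0.48 for CCL3, and those with BAY1238097 -0.45 for CCDC106 and -0.43 for VPREB3. Without the 24 h arrays they were 0.48 for ADM, 1.18 for UBA1 and 1.25 for EIF5A in DMSO and -1.41 for CCDC106 with BAY1238097. The counts for DMSO and BAY1238097 were 93 and 118 under background correction with median scaling and 0 and 25 with hours in place of their logarithm, both were 0 under median scaling alone, 321 passed in DMSO without a filter on dim probes and 48 with BAY1238097 with array weights. Without a filter the DMSO slopes of ADM, S100A4, UBA1, EIF5A, CCL4L1 and CD83 were lost (adjusted p from 0.0513 to 0.0905), as was that of CCDC106 with BAY1238097 (0.0531). With array weights ADM and S100A4 were lost in DMSO (0.0753 and 0.0521) and ANKRD37, RNA18SN5, CITED2, FASN, CCDC106 and VPREB3 with BAY1238097 (0.0535 to 0.140). Background correction with median scaling lost EIF5A (0.0633), and median scaling alone lost all the slopes named here (0.0582 to 0.0948).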

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

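Of the tests in this part, those of S phase and of cross-hybridization for the histone genes, that of the other MYC probe, the shuffles for the effects that changed with time and the list splits with the time factor were chosen after the results were seen. Among 378 sets of 4 values in a group (named genes and array measures), 31 held a time point far from the other 3 by Dixon's test, which chance alone gives for about 1 set in 20. The 4 values of a group are different times, so such a value can be an early or late level rather than a faulty array. In the BAY1238097 group the 4 h array stood above the later ones, on the log2 scale, for TNFRSF17 (8.87), BBOX1 (8.79), MLKL (7.38), PVRIG (7.68), CCDC112 (10.31), SLC15A3 (9.42), ISG20 (11.51), HEXIM1 (7.32) and ZCCHC24 (7.42), and below them for MAP3K7 (9.996) and ZFP36 (11.61). The 24 h array of that group stood low for POLE2 (7.75) and high for PTPN6 (6.90) and IL21R (6.95), and the 8 h array stood low for SERPINA9 (6.66), MAP1LC3B (9.54) and PFKP (9.40) and high for TRAF1 (7.82) and SESN3 (8.13). In DMSO the 24 h array stood high for COBL (9.66), MAP1LC3B (8.94) and CD38 (11.19) and low for CD27 (9.39), CXCL9 (8.47) and MT2A (8.55), the 4 h array stood low for MAP3K7 (9.22) and high for NDUFC1 (8.91) and IL21R (7.61), and the 12 h array stood high for NEU1 (8.01) and low for ASNS (9.85). The DMSO array at 24 h also had 19122 probes above background, against 18534 to 18585 on the other 3.

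For 28 named genes the treatment effect changed with time by the interaction test. The slopes per doubling of time were positive for RGS1 (0.74), CBLB (0.72), PRDM1 (0.67), CFLAR (0.63), PIK3CG (0.63), MYC (0.54), CD83 (0.43), BCL2 (0.39), CD69 (0.36), NFKBIE (0.36), NFKBIZ (0.35) and IFIT2 (0.32). They were negative for FASN (-0.84), MZB1 (-0.84), MT1X (-0.79), PVRIG (-0.77), VPREB3 (-0.77), ATF3 (-0.66), RPL29 (-0.64), H2BC8 (-0.58), ASNS (-0.52), HLA-DOB (-0.51), POLE2 (-0.49), RPS7 (-0.48), IRF7 (-0.44), TM7SF2 (-0.42), UNG (-0.40) and RRM2 (-0.37). By camera on the same coefficient, 12 lists shifted, and 0 with an estimated correlation. Their adjusted p-values were 4.84e-19 for DNA replication and E2F targets, 1.62e-07 for heat shock and unfolded protein response, 2.90e-07 for MYC targets of metabolism and translation, 3.41e-07 for mitosis, 5.52e-06 for NF-kappaB targets, 2.22e-05 for MHC class II presentation, 3.99e-05 for glycolysis, 4.95e-05 for interferon response and for cholesterol synthesis, 0.00193 for oxidative phosphorylation, 0.00420 for anti-apoptotic regulators and 0.00738 for lysosome and autophagy. Among 4774 probes above background without a gene name here, 804 differed between treatments (430 higher, 374 lower), which is 16.8% of them against 30.3% of the named genes.

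The rise of the histone genes at all 4 times was set against 3 technical or indirect explanations. More cells in S phase would raise DNA replication genes as well. The mean difference of that list over the 4 times was -0.19 (SE over times 0.17) against 1.60 (SE 0.034) for the histone list. Its medians went from 0.13 at 4 h to -0.60 at 24 h, while those of the histone list were 1.63 and 1.68. The replication list thus showed no rise of the size of the histone genes. Its spread does not exclude a small rise, so a part of S phase stays open. Binding of 1 rising transcript to many probes would stay within a family, but all 5 histone families held a called rise of at least 1. The families did not rise alike. The medians were 1.75, 1.78 and 1.66 for H1, H2A and H2B, and 0.42 and 0.54 for H3 and H4. In H3 1 of 9 genes and in H4 2 of 8 genes had a called rise of at least 1. A regional rise of the chromosome 6 cluster would lift its neighbours, but 11 non-histone genes within it had a median change of -0.12 (SE over genes 0.10, over times 0.036). An effect of the treatment on histone transcripts may also account for the rise, and a longer poly(A) tail or better capture of these transcripts during labelling was not tested.

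The treatment effects that grew or shrank over time were set against the dimmer treated arrays at 8 to 24 h and against chance. Brightness differed by -0.015, -0.23, -0.21 and -0.31 on the log2 scale at 4, 8, 12 and 24 h. Over the 367 genes the 24 h difference fell on the 12 h minus 4 h difference within DMSO with a slope of -0.77 (SE 0.056), against -0.42 predicted from brightness and -0.18 (SE 0.0093) over all genes. Choosing genes by the change of their difference steepens this slope by itself, to -0.69 (median of 50 shuffles over genes that kept the relation of all genes, from -0.87 to -0.58), so the test decides nothing. Brightness therefore stays open, as does a treatment that counteracts the drift of the vehicle group. Of the 8 splits that part every time point 1 gave as many genes (the real one, 367, highest other 0), too few splits for a share under 0.05.

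The narrowing fall of MYC was set against a probe fault and against brightness. The other MYC probe narrowed by 1.30 between 4 and 24 h, against 1.40 for the brightest one, but the groups behind it differed: at the brightest probe BAY1238097 moved by 1.51 and DMSO by 0.12, and at the other by 0.34 and -0.96. Over 815 probes as bright as that of MYC, the median change was -0.029 (SE 0.017), and 0.123% of them changed by at least as much. Quantile normalization gives every array the same distribution, which holds such a median near 0 whatever the brightness. The median therefore decides nothing, and brightness stays open for MYC. Since both probes narrowed, a narrowing of the difference may be a hypothesis. The probes leave open whether MYC rose under treatment or fell in the vehicle group. Its interaction call was lost after background correction with quantile and median scaling, with array weights and without the time factor, with slopes of 0.58, 0.60, 0.47 and 0.54 and adjusted p-values of 0.0676, 0.0936, 0.0836 and 0.120.

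Of the 35 splits of the 8 arrays into 4 and 4, 8 part every time point, the real one included. The arrays of a time are pairs, so the splits that leave them together are not like the real one and decide nothing. For the count of genes changed by treatment without the time factor, 1 of the 35 gave as many: the real one, with 1485, against 189 for the highest other, which parts 4 and 8 h from 12 and 24 h and not the pairs. With the time factor the real split gave 3161 and the highest other of the 8 splits that part every time point gave 0. The splits number 8, 1 of them the real one, which is too few for a share under 0.05. For the lists without the time factor 3 of the 35 splits moved at least 16, the real value, and the highest other moved 17. With the time factor the real split moved 18 lists and the highest other of the 8 that part every time point moved 14, again too few splits for a share under 0.05.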

How the results depend on the processing

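The neqc fit with quantile normalization and the median scaling alone were chosen after seeing the data; the other settings were fixed before. The deposited log2 values and quantile normalization without background correction are the values reported, so they change nothing by construction. The count of genes changed by treatment (3161) was 4885 with array weights, 135 with an absolute log2 change of at least 1 as well and 1485 without the replicate block (the time factor), and 1276 to 4124 with a time point or array left out. With the time factor in the model, leaving out 1 array gives the same result as leaving out its time point. For treatment, treatment by time and the lists, the fits without 1 array are therefore no separate check. Of the 3161 genes, 2496 were shared with neqc and median scaling, 2343 with median scaling alone and 1484 without the block. The count for treatment by time (367) was 0 with neqc under either scaling, with array weights, without the replicate block and with hours, and 157 to 1300 with a time left out. The DMSO trend (809) was 93 with neqc and median scaling, 321 without a filter, 0 with hours or median scaling, and 0 to 2156 with a time or array left out. The BAY1238097 trend (954) was 118 with neqc and median scaling, 48 with array weights, 25 with hours, 0 with median scaling, and 1 to 1447 with a time or array left out. The number of shifted lists (18) was 0 with an estimated correlation and 14 to 17 with a time or array left out. The cause was not tested, except that adding a threshold lowers a count by construction. Leaving out arrays lowered some counts and raised others, among them treatment without the 4 h arrays (4124) and each time comparison without the 24 h arrays (1300, 2156 and 1447). Of 124 named genes, 32 lost their treatment call without the replicate block, 31 without the 8 h and 30 without the 12 h arrays, 3 without the 4 h and 4 without the 24 h arrays, 10 under median scaling, 8 under neqc with median scaling and 8 without a filter. Of the 42 genes named after their values were seen, 29 lost it without the block, 28 without the 8 h, 29 without the 12 h, 14 without the 24 h and 5 without the 4 h arrays, 16 under median scaling, 15 and 12 under neqc with median and with quantile scaling, 8 without a filter, 5 with a variance trend and 1 of 34 with the strict filter. Of 31 calls named for the time comparisons, 21 were lost under median scaling, 19 with array weights and 19 without the 4 h or the 8 h arrays. BCL2 alone changed sign (-0.31 to 0.031 with a time left out). Medians of 9 uncalled lists came with a turned test direction or sign. MYD88 and Toll-like receptor signalling was -0.083 without a filter, -0.081 with neqc and median scaling, -0.080 with median scaling, -0.0070 with the strict filter and -0.013 to 0.016 with a time left out, and JAK and STAT signalling was -0.028 with median scaling. Mitosis was -0.12 with neqc and median scaling, -0.14 with median scaling and -0.058 to 0.14 with a time left out. NF-kappaB targets were -0.18 with neqc and median scaling, -0.10 with median scaling, 0.10 with the strict filter, -0.044 with every probe, -0.041 without the block and by fry, and -0.10 to 0.027 with a time left out. Pro-apoptotic genes were 0.030 without a filter, 0.078 with the strict filter, 0.015 with every probe, -0.072 with median scaling, -0.059 with neqc and median scaling and -0.0185 to 0.055 with a time left out. Anti-apoptotic regulators were -0.013 with the strict filter and -0.099 to 0.017 with a time left out. Cholesterol synthesis was -0.026 without the block and by fry, -0.21 with median scaling and -0.094 to 0.091 with a time left out. Myeloid markers were 0.22 with the strict filter and -0.029 to 0.0011 with a time left out, and stromal, endothelial and epithelial markers were -0.023 without a filter. The variance model with a trend was not run for lists. Signal over background limits dim genes. In a comparison chosen after seeing the data, background correction with quantile normalization widened the SD of log2 changes 2.24 times over the dimmest 3481 genes, 1.47 times over the middle 3481 and 1.12 times over the brightest 3481.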

Other observations

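The gene families in this part, and the members named, were chosen after their values were seen, and the test against cytosolic ribosomal proteins after the result. Among mitochondrial ribosomal protein genes more fell than rose with BAY1238097. Of 76 measured, 30 fell and 1 rose, with a median of -0.20 (SE 0.028) and medians of -0.09, -0.17, -0.20 and -0.30 at 4, 8, 12 and 24 h. MRPL34 fell by 0.80 ± 0.06, MRPL3 by 0.65 ± 0.07 and MRPS17 by 0.63 ± 0.07, while MRPL10 rose by 0.25 ± 0.07. The median lay below all of 10000 random lists matched on brightness (lowest -0.17), as a description, since the family was picked for its fall, and it was -0.38 under median scaling. The rise of MRPL10 was lost without the 4, 8 or 12 h arrays (adjusted p = 0.0669, 0.174 and 0.110), with the time point left out of the model (0.0675), with a variance trend (0.0580), after background correction with quantile or median scaling (0.0503 and 0.209) and under median scaling (0.361), so that 0 of the 76 rose under the other normalizations. A fall common to all ribosomal protein genes would lower the cytosolic list too. Its median was 0.019 (SE over genes 0.039), with medians of 0.0052, 0.013, 0.051 and 0.014 at 4, 8, 12 and 24 h. For the list as a whole these values argue against a common fall. Single members went both ways, and their SD of 0.27 exceeds the distance of the list from the mitochondrial median.

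Subunits of RNA polymerase I, which transcribes ribosomal RNA, fell with the nucleolar genes: 6 of 8 fell and 0 rose (median -0.36), POLR1G by 0.65 ± 0.08 and POLR1H by 0.47 ± 0.06. Among the subunits, POLR1B, POLR1C and POLR1D are also members of the nucleolar list, so the counts overlap. The MXD genes, which encode antagonists of MYC at MAX, rose in 3 of 3 cases, MXD4 by 1.04 ± 0.15, MXD1 by 0.86 ± 0.11 and MXD3, above background on 2 of 4 DMSO and 3 of 4 BAY1238097 arrays, by 0.37 ± 0.10. MXD3 lost its call without the 8, 12 or 24 h arrays (adjusted p = 0.146, 0.1501 and 0.0779) and without a filter on dim probes (0.0598), and MXD4 and MXD3 with the time point left out of the model (0.0740 and 0.187). Of 5 metallothionein genes 4 rose and 0 fell, MT2A (1.60 ± 0.12), MT1X (1.60 ± 0.30), MT1H (0.48 ± 0.12, above background on 3 of 4 arrays of each group) and MT1F (0.40 ± 0.06), and all 5 rose after background correction. The family's median went from 0.75 at 4 h to 0.38 at 24 h. The calls of MT1X and MT1H were lost without the 8 h arrays (adjusted p = 0.0579 and 0.107), that of MT1H without the 12 h arrays (0.0604), and those of MT1X, MT1F and MT1H with the time point left out of the model (0.138, 0.455 and 0.162). The metallothionein genes are close copies, so their probes cannot be fully separated. The sestrins SESN1 (0.45), SESN2 (0.26, above background on 1 of 4 DMSO arrays) and SESN3 (0.68) rose, with SESN2 lost without the 8 or 12 h arrays (adjusted p = 0.0933 and 0.0804) and with the time point left out of the model (0.241). SESN1 and SESN2 are also in the list of p53 targets, and SESN3 is in that of quiescence. The signs of the medians of these families were the same under background correction and under median scaling.

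Gene length was tested as a hypothesis with a negative result. If short genes were raised, length and log2 change would correlate below -0.1, but Spearman's rho across 10437 genes was 0.045, with median lengths of 29.1 kb for higher and 24.0 kb for lower genes.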
